A study of Mus musculus with 24 samples.

How the data were processed

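EU-labelled RNA was profiled in 24 libraries of E14TG2a mouse embryonic stem cells, 2 for each of 3 genotypes and 4 labelling times (10, 20, 40 and 60 min with 1 mM EU). Per the labels' protocols, the cells grew in serum medium with LIF and the inhibitors PD0325901 and CHIR99021, which block MEK and GSK3. RNA from EU-labelled Drosophila cells was added in equal amount to each sample, labelled RNA was captured with a click-chemistry kit, and libraries were made with a stranded total RNA kit (SMARTer v2). HISAT2, SAMtools, Picard and the mouse genome build GRCm39 are named per the submitters' processing notes. Their versions, the read counter, its use of strand, the annotation of genes and repeats and the treatment of reads that fit several places are not given in the sources used here. Reads of overlapping genes, antisense genes and near-identical copies are uncertain for that reason.

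The authors deposited a table of 56941 genes and another of 4929385 repeat loci, named by class, family and position. Per the file headers and values, each deposited value is a log2 ratio of a genotype at 20, 40 or 60 min to the same genotype at 10 min, after scaling to spike-in reads and with both replicates combined. The columns use the prefixes wt, ko and ki, and ki was taken as dcIDR because it is the remaining genotype. The line for the spike-in is 0 throughout and was left out of all tests.

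Reads per library were then worked out from the ratios. Every value that is not 0 equals, within a relative error of 6e-15, a ratio of sums of whole reads, each divided by the spike-in reads of its library, times a constant of 40000, plus 1. Solving for the whole numbers returned the reads of all 24 libraries, the 10 min ones included, for 100% of the lines with a value that is not 0 in both tables. Recovery was tested on simulated data, where the sum over a group was right in 100% of 3000 genes at each of 6 depths. The split between both libraries of a group was right for all 8 libraries of a genotype in 98.9% of genes at a mean of 300 reads, 77.8% at 1000 and 43.0% at 3000. Where several splits were possible, the one nearest the pair's median log2 ratio was then taken, a step that was not simulated. It counted as clear if it lay within 0.6 and the next at least 0.8 away. In WT at 60 min 7517 gene lines had several splits and 2848 stayed unclear, so the spread of the others may be understated. Among tested genes 2848 (12.7%) had at least 1 unclear split, each of them at 60 min in WT and some in other groups too, and there the group's sum was shared out by the median ratio of both libraries, which gives a mean but no spread. Which library carries which replicate number cannot be read from the values, so the library with more spike-in reads was called A and the other B.

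The level of a gene is its reads scaled to a common 11714 spike-in reads, the geometric mean over the libraries. Libraries held 26810 to 34172 genes with reads, 1.32 to 2.37% of reads on mitochondrial genes and 12.4 to 14.7% in the 100 genes with most reads. Intervals from read counts would cover counting error only, and none is given. Whether mates were counted separately, which would make such intervals too narrow, is not known here. Genes with a mean level of at least 10 and a level above 0 in at least 6 libraries were tested, 22448 in all. Levels were tested as log2(level + 1), a scale on which the change of low genes is understated. Values were compared on separate scales: the deposited spike-in scale, and the same values relative to the median tested gene of each library, on which a difference between genotypes that all genes share is removed.

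Each gene was fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient for each of the 12 groups and all 24 libraries sharing the estimate of the spread. A genotype difference is the mean of the differences at the 4 times. Its dependence on labelling time was tested with limma's F test on 3 contrasts, and the trend with time as the slope per doubling of minutes. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Totals were compared by exact two-sided permutation of genotype within labelling time. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The planned fry test, which does not set a list against the other genes, used the genes without an unclear split. Each test was adjusted over the 23 lists. Where no test is named, p-values of lists are those of camera at the preset correlation. Repeats were summed over class and family, 60 of 61 names passing the filter; subfamily names such as L1Md_T or MERVL-int, planned beforehand, had no match because the loci carry only class and family. Single loci were tested by the same fit relative to the median locus of each library, 306027 of the 2172946 with reads passing the filter. For regions, loci were summed in windows of 1 and 0.25 Mb and each library was set to its median window.

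The comparisons, filters, gene lists and the other settings not marked below as later additions were fixed before the data were examined. The genes named are, for each mutant against WT, the 10 largest rises and falls that passed, had 1 sign at all 4 times and lay above the median level, and up to 4 called members of each list with the smallest p; predicted genes and pseudogenes are not named. For dcIDR against KO the 5 largest each way are named. Some genes that meet these rules are not reported here. Planned count tests assumed deposited counts. As the deposited values are log2 ratios, limma was used throughout and count tests on the recovered reads were left out; limma voom on the recovered reads was added as an alternative after seeing the data. Gene names and chromosomes came from an annotation of the earlier mouse build GRCm38 (GENCODE M21), matched by identifier for 51948 genes, of which no coordinates are printed; 21523 tested genes had a chromosome, and medians of whole chromosomes are over those with a mean level of at least 50. Positions of repeats are those of the deposited tables in GRCm39.

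The fits were tested on simulated data with 50 planted changes of each size among 22448 genes. For KO against WT 48% of planted differences of 0.50 (log2), 74% of 1 and 92% of 2 were recovered with 6 false calls, and for dcIDR against WT 36%, 72% and 98% with 9. For dcIDR against KO 46%, 72% and 100% were recovered with 7 false calls. A difference of 1 at 10 min alone was found in 28% of genes for KO with 9 false calls and in 34% for dcIDR with 2. Noise in these simulations was independent between genes and libraries, and no library split was unclear. Variation that the genes of a library share was therefore not covered, and false calls in the real libraries may be more numerous. Alternatives covered the scale, the centring, the filter, the pseudocount, library weights, the libraries in the fit, each library left out in turn, and, chosen after seeing the data, leaving out the 10 min libraries or the genes of chromosomes 4, 6, 8, 11 and X. Further tools were data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and g++ 11.4.0.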

Results

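RNA made during short labelling windows was measured in mouse embryonic stem cells of the E14TG2a line. The cells took up EU (5-ethynyl uridine), a uridine analog that RNA polymerases build into growing transcripts, at 1 mM for 10, 20, 40 or 60 min, and the labelled RNA was captured by click chemistry and sequenced. Per the labels, cells were unmodified (WT), had a knockout of Alkbh5 (KO), or carried Alkbh5 without its C-terminal intrinsically disordered region (dcIDR). ALKBH5 is an enzyme that removes the N6-methyl mark (m6A) from adenosines of RNA. The 3 genotypes and 4 labelling times gave 12 groups of 2 libraries, 24 in all. The labels state that the same amount of EU-labelled Drosophila RNA went into every sample, so reads per spike-in read give the amount of captured RNA. The libraries held 3133126 to 22158292 reads over genes, 3654850 to 22127036 reads over repeats and 6037 to 23382 spike-in reads. Each genotype is 1 line as far as the labels tell, and replicates are separate dishes at most, so p-values measure only the spread between these samples. Differences between genotypes are given as log2 values averaged over the 4 labelling times, with 8 libraries per genotype, followed by their standard error. Where no scale is named, values of genes are relative to the median gene of each library. Of 223 named gene results, 72 no longer passed on the deposited scale and 5 changed sign.

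Reads over Alkbh5 (ENSMUSG00000042650, chromosome 11) were present in every library. The 8 WT libraries had 1171 and 361 reads at 10 min, 1420 and 784 at 20 min, 2335 and 2669 at 40 min, and 2900 and 3212 at 60 min. The KO libraries had 1037 and 384, 966 and 340, 1335 and 1613, and 1989 and 1524 reads at the same times. The dcIDR libraries had 247 and 242, 1463 and 1251, 2215 and 2024, and 2269 and 1892 reads. Scaled to a common number of spike-in reads, the WT level was 480 ± 150 (SD, n = 2) at 10 min and 3210 at 60 min, where the split between both libraries was unclear. The KO level was 596 ± 44.6 at 10 min and 2297 ± 110 at 60 min, and the dcIDR level was 208 ± 38.8 and 2343 ± 395 (SD, n = 2). Relative to the median gene of each library, Alkbh5 lay lower in KO than in WT, at −0.60 ± 0.05 (limma, adjusted p = 1.44e-09) and in dcIDR, at −0.46 ± 0.05 (limma, adjusted p = 2.67e-07). Both libraries of either mutant lay below both WT libraries at 10, 20 and 40 min on that scale, and at 60 min below the WT level, which there is a single value. On the deposited spike-in scale neither difference passed, at −0.29 in both (limma, adjusted p = 0.100 for KO and 0.20 for dcIDR). Reads summed over a whole gene cannot show whether the edited part is missing, and so check neither deletion.

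The first comparison asked how much labelled RNA the genotypes held. Labelled mRNA-table reads per spike-in read in WT were 386 ± 74.0 at 10 min, 711 ± 43.0 at 20 min, 1605 ± 477 at 40 min and 1825 ± 358 at 60 min (SD, n = 2 each). KO held 638 ± 94.3, 863 ± 88.3, 1485 ± 128 and 2171 ± 123 at these times (SD, n = 2). dcIDR held 255 ± 7.41, 1188 ± 375, 1942 ± 346 and 1909 ± 419 (SD, n = 2). Averaged over the times, KO lay 0.30 above WT on the log2 scale, with an exact two-sided permutation p = 0.0478 over all arrangements within labelling time and 0.144 after adjustment over the 3 genotype comparisons. Without WT library B of 40 min the difference was 0.37 and passed (adjusted exact permutation p = 0.0139). The dcIDR difference from WT was 0.12 (adjusted exact permutation p = 0.537), and that of dcIDR from KO was −0.18 (adjusted exact permutation p = 0.537). Repeat-table reads differed alike, by 0.30 in KO (adjusted exact permutation p = 0.139), 0.14 in dcIDR (0.495) and −0.16 between dcIDR and KO (0.495). The averages hide opposite signs: dcIDR differed from WT by −0.58 at 10 min and by 0.70 at 20 min, while KO differed from WT by 0.73 at 10 min and by −0.08 at 40 min. Without the 10 min libraries, a setting chosen after seeing the data, the mRNA total of dcIDR lay 0.20 above that of KO, against −0.18 with all times. For mRNA the later difference of dcIDR from WT minus that at 10 min was 0.94 (exact permutation p = 0.0170, adjusted 0.0509), and for repeats 1.06 (exact permutation p = 0.0139, adjusted 0.0417).

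**Figure D1:**
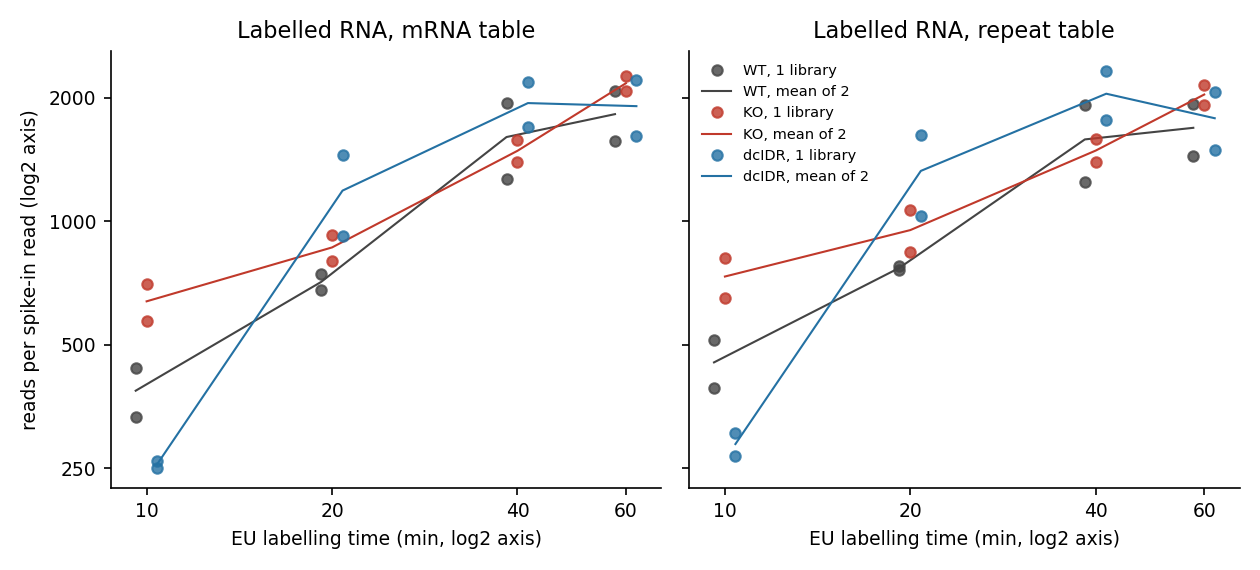
Labelled reads per spike-in read (log2 axis) in each of the 24 libraries against EU labelling time in minutes (log2 axis), for the mRNA table and the repeat table, with 1 point per library, a line through the group means, and the genotypes set slightly apart sideways. At 10 min the dcIDR libraries lie lowest and the KO libraries highest, and at 20 min the dcIDR mean lies highest.

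In the cells labelled KO, labelled RNA of the secreted Nodal inhibitors Lefty2 and Lefty1 rose against WT by 1.40 ± 0.06 and 1.36 ± 0.11, relative to the median gene. Ina (alpha-internexin, a neuronal filament protein) rose by 1.43 ± 0.12 and Mir124a-1hg, host of a brain microRNA, by 1.36 ± 0.10. Nlrp4a and Nlrp9c, members of a family expressed in oocytes, fell by 3.01 ± 0.13 and 2.36 ± 0.10, and Dcdc2a, a doublecortin-domain gene, fell by 2.90 ± 0.08. The citrate transporter gene Slc13a5 fell by 2.45 ± 0.06 (limma, adjusted p = 5.00e-20) and the sodium-glucose transporter gene Slc5a1 fell by 2.13 ± 0.08.

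Of 22448 genes tested, 3488 were higher and 3798 lower in KO than in WT at an adjusted p under 0.05 (limma), 226 and 492 of them by more than 2-fold. In 6387 of these 7286 genes the difference had 1 sign at all 4 labelling times. Further large rises were Fbn1 (fibrillin-1 of the extracellular matrix) at 1.63 ± 0.10, Atp2b2 (a plasma membrane calcium pump) at 1.57 ± 0.09, Vax2os at 1.45 ± 0.11, Nphs1 (nephrin) at 1.37 ± 0.07 and Sox4 (a transcription factor) at 1.35 ± 0.10. Other large falls were Sntg1 (a syntrophin) at −2.67 ± 0.12, Adgrg6 (an adhesion receptor) at −2.44 ± 0.10, Ak9 (an adenylate kinase) at −2.12 ± 0.10, Pkd1l2 at −2.09 ± 0.12 and Ephx2 (an epoxide hydrolase) at −2.07 ± 0.13. Atp2b2 and Vax2os lie on chromosome 6, whose genes shifted as a whole, and Vax2os is an antisense gene, whose reads cannot be told from its partner's where counting ignores strand. On the deposited spike-in scale the median gene lay 0.30 higher in KO, and 6357 genes were higher and 665 lower. Without the 10 min libraries 2251 were higher and 709 lower on that scale, and without genes of chromosomes 4, 6, 8, 11 and X 3362 and 509.

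Of 23 gene lists fixed beforehand, 5 moved together in KO by the camera test. ATF4 targets of the integrated stress response were higher in 17 and lower in 2 of 26 members, with 21 called when adjusted over the list alone (adjusted p = 1.12e-08). Its examples were Mthfd2 (mitochondrial folate metabolism, 0.85 ± 0.05), the glycyl-tRNA synthetase gene Gars (0.57 ± 0.04), Herpud1 (endoplasmic reticulum protein quality control, 0.97 ± 0.08) and Psat1 (serine synthesis, 0.41 ± 0.04). Mthfd2 and Gars lie on chromosome 6 and Herpud1 on chromosome 8, and without the genes of chromosomes 4, 6, 8, 11 and X the list still stood apart (adjusted p = 3.07e-08). Cholesterol synthesis genes were higher in 17 and lower in 1 of 25, 20 when adjusted over the list alone (adjusted p = 7.16e-07), with Msmo1 at 0.71 ± 0.05, Idi1 at 0.47 ± 0.06 and Lss at 0.37 ± 0.05. Genes of the 2-cell-like state, a rare condition of stem cell cultures that resembles the 2-cell embryo, were higher in 12 and lower in 3 of 21, 15 when adjusted over the list alone (adjusted p = 0.00128). They included Zscan4a at 0.98 ± 0.11, Zscan4c at 0.86 ± 0.09 and Zscan4e at 0.72 ± 0.07, while Eif1a fell by 0.32 ± 0.04, a call lost as deposited (−0.012, adjusted p = 0.953). On the deposited scale the calls numbered 21 higher and 0 lower for ATF4 targets, 20 and 0 for cholesterol synthesis genes, and 16 and 0 for 2-cell-like genes.

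p53 targets fell in KO relative to the median gene, with 13 of 23 lower and 3 higher, 17 when adjusted over the list alone (adjusted p = 0.000341, but 0.105 as an adjusted p with an estimated correlation), and on the deposited scale 4 were higher and 0 lower, the median turning from −0.21 to 0.10. Plk2 (−0.59 ± 0.04), Polk (a DNA polymerase, −0.42 ± 0.05), Mdm2 (the ubiquitin ligase of p53, −0.38 ± 0.03) and Trp53inp1 (−0.38 ± 0.04) led them. Neural markers were higher in 4 and lower in 1 of 9, 5 when adjusted over the list alone (adjusted p = 0.00519), although the list's median of −0.01 and mean of 0.21 differ in sign and as deposited its median is 0.30, with 4 higher and 1 lower. Pax6 rose by 1.57 ± 0.11, Nes (nestin) by 0.86 ± 0.05 and Tubb3 (a neuronal tubulin, on chromosome 8) by 0.84 ± 0.07, while Pou3f2 fell by 1.49 ± 0.19. All of these list calls but that of the p53 targets also passed with an estimated correlation. The p53 targets did so without the 10 min libraries (adjusted p = 0.0110) and without genes of chromosomes 4, 6, 8, 11 and X (0.0344).

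The remaining 18 lists did not pass in KO, although single members did. Of m6A writers, erasers and readers 4 were higher and 4 lower of 22 (9 when adjusted over the list alone), with the second m6A demethylase gene Fto (chromosome 8) at 0.46 ± 0.05 and Igf2bp3 (chromosome 6) at 0.58 ± 0.04. Naive pluripotency genes were higher in 6 and lower in 10 of 27 (17 when adjusted over the list alone, adjusted p = 0.0589), led by the transcription factor genes Tfcp2l1 at −0.61 ± 0.03 and Sox2 at −0.42 ± 0.04. Formative and primed genes were higher in 6 and lower in 7 of 20 (15 when adjusted over the list alone), with the DNA methyltransferase genes Dnmt3b at −1.16 ± 0.05 and Dnmt3l at −1.21 ± 0.07. Endoderm and mesoderm markers were higher in 1 and lower in 4 of 15 (5 when adjusted over the list alone), trophoblast markers in 3 and 3 of 10 (6), and fibroblast markers in 1 and 3 of 9 (4). Interferon genes were higher in 8 and lower in 4 of 19 (13 when adjusted over the list alone), glycolysis genes in 8 and 5 of 23 (15), and immediate early genes in 9 and 5 of 25 (15). MAPK feedback targets were higher in 8 and lower in 3 of 17 (12 when adjusted over the list alone), Wnt targets in 3 and 4 of 12 (7), and histone modifying enzymes in 6 and 19 of 46 (26), among them Kdm2b at −0.61 ± 0.04 and Ezh2 (chromosome 6) at 0.47 ± 0.04. RNA polymerase II and elongation genes were higher in 8 and lower in 6 of 42 (15 when adjusted over the list alone), cell cycle genes in 8 and 7 of 31 (15), and imprinted and germline genes in 5 and 11 of 24 (18). Ribosomal protein genes were higher in 7 and lower in 14 of 89 (20 when adjusted over the list alone), replication-dependent histones in 1 and 9 of 63 (7), and genes named Zfp in 63 and 78 of 347 (144), with Zfp951 at −1.20 ± 0.05. As deposited, the balance turned from even to higher for m6A genes (6 higher, 0 lower) and trophoblast markers (5 and 2), and from lower to higher for 10 of these 18 lists. The latter included histone modifying enzymes (11 higher, 0 lower), naive pluripotency genes (10 and 0), imprinted and germline genes (8 and 3), formative and primed genes (10 and 4) and ribosomal protein genes (11 and 1). The others of the 10 were replication-dependent histones (6 and 0), Zfp genes (107 and 11), endoderm and mesoderm markers (5 and 0), fibroblast markers (1 and 0) and Wnt targets (4 and 0). In the remaining 6 lists the falls were lost or reduced to 1, with 13 higher and 0 lower for cell cycle genes, 10 and 0 for RNA polymerase II and elongation genes, 10 and 0 for glycolysis genes, 9 and 0 for MAPK feedback targets, 8 and 0 for interferon genes and 13 and 1 for immediate early genes. Without genes of chromosomes 4, 6, 8, 11 and X the naive pluripotency list (adjusted p = 0.00501, and 0.00234 as an adjusted p with an estimated correlation) and the histone modifying enzymes (0.0116 and 0.0219) also passed as lower in KO. With all genes neither passed, at an adjusted p of 0.741 for both with an estimated correlation, and their medians were 0.22 and 0.25 as deposited.

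Genes of whole chromosomes were displaced together in KO. Among genes with a mean level of at least 50, the 782 of chromosome 6 had a median difference of 0.41 from WT, 588 being higher and 33 lower, and the 780 of chromosome 8 had a median of 0.34, 576 higher and 31 lower. Reads over repeats in windows of 1 Mb showed the same shift, with a median of 0.36 over chromosome 6 and 0.33 over chromosome 8, and also in chromosome 11 between 13 and 57 Mb (GRCm39), where 42 windows had a median of 0.40 against −0.03 elsewhere on the chromosome. Without genes of chromosomes 4, 6, 8, 11 and X, a setting chosen after seeing the data, 1579 genes were higher and 3029 lower in KO. Libraries stayed centred on the median of all tested genes, and the kept autosomes had medians from −0.055 (chromosome 13) to −0.008 (chromosome 5). Part of the excess of lower genes cannot be told apart from this offset.

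**Figure D2:**
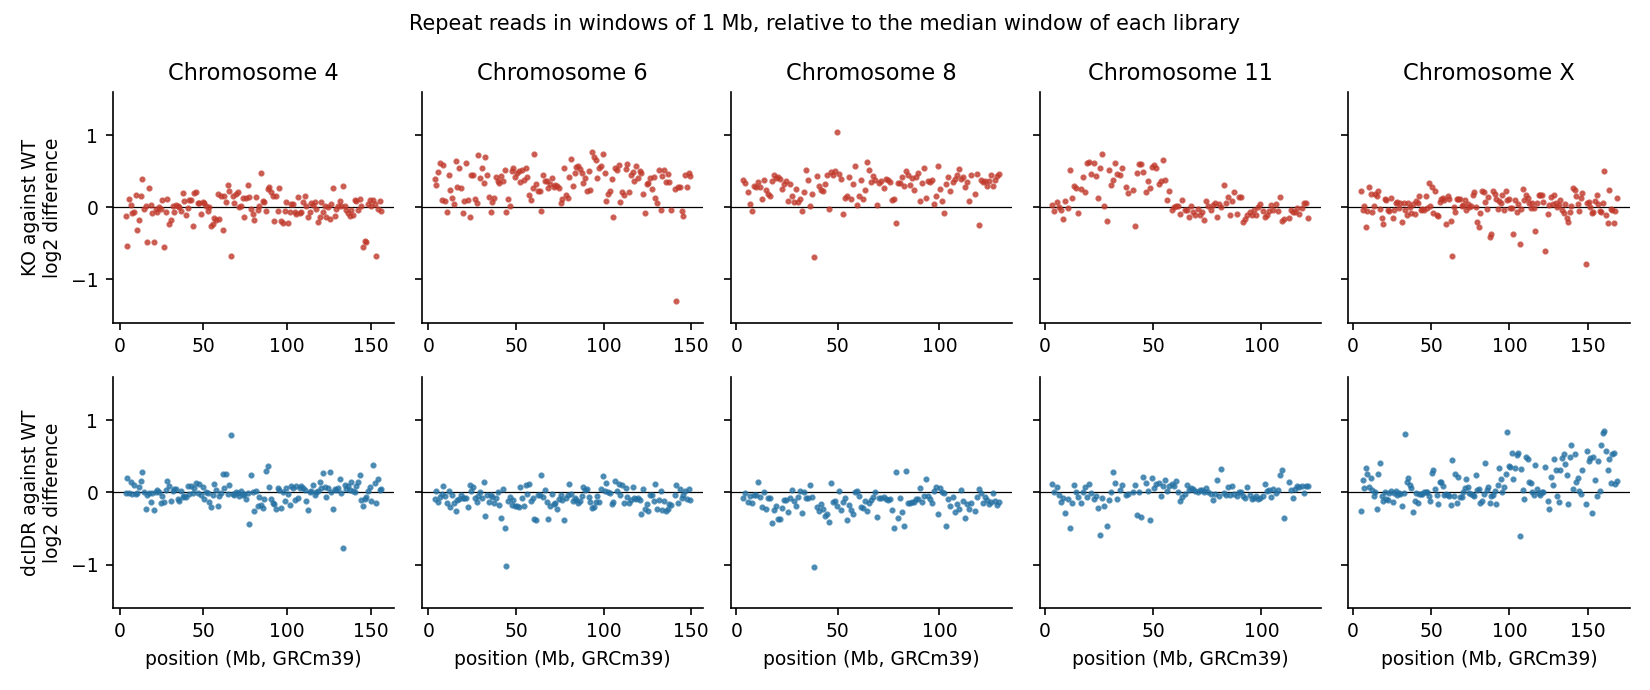
Log2 differences of KO and of dcIDR from WT in repeat reads, relative to the median window of each library, against position in Mb (GRCm39) on chromosomes 4, 6, 8, 11 and X, with 1 point per window of 1 Mb. In KO most windows of chromosomes 6 and 8 and of chromosome 11 from 13 to 57 Mb lie above 0, and in dcIDR 1 window of chromosome 4 lies at −0.77 and many windows of the last part of the X chromosome lie above 0.

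**Figure D3:**
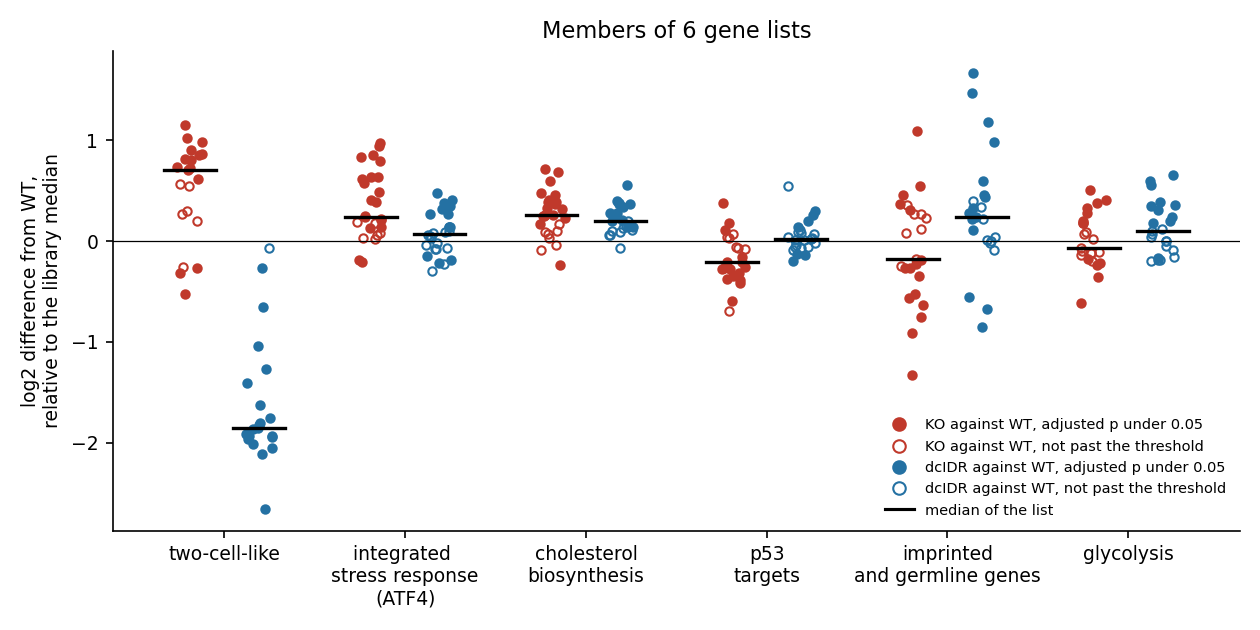
Log2 differences of KO and dcIDR from WT, relative to the library median, for the members of 6 gene lists, with 1 point per gene (filled where its adjusted p was under 0.05) and a bar at the list median. The 2-cell-like median is 0.70 in KO and −1.86 in dcIDR, and the KO medians of the p53, imprinted and germline, and glycolysis lists, which lie below 0 here, lie above 0 as deposited.

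The cells labelled dcIDR were compared with WT next. Zscan4d, Zscan4a, Zscan4e, Zscan4c and Zscan4f, genes switched on in the 2-cell embryo, lay at −1.94 ± 0.09, −1.94 ± 0.11, −1.86 ± 0.07, −1.86 ± 0.09 and −1.81 ± 0.12 relative to the median gene, and all 5 fell. The growth factor gene Fgf10 fell by 1.90 ± 0.11 and Dab2, an endocytic adaptor expressed in extraembryonic endoderm, by 1.62 ± 0.10. Scml2, a Polycomb-group gene of the male germ line, rose by 2.31 ± 0.09 (limma, adjusted p = 3.30e-15), and Taf7l, a germ-cell subunit of the general transcription factor TFIID, by 1.67 ± 0.17. Both lie on the X chromosome.

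In dcIDR 2592 genes were higher and 3769 lower than in WT (limma), 198 and 382 by more than 2-fold, and in 4783 of the 6361 the difference had 1 sign at all 4 times. The balance turned to 2799 higher and 2287 lower without the filter on low levels, and with quantile normalization 48.4% of the changed genes were higher, against 40.7%. The other large rises were Nxf3 (of the RNA export factor family) at 1.43 ± 0.11, S100a13 at 1.32 ± 0.10, Morc4 at 1.17 ± 0.09, Nup62cl at 1.14 ± 0.08, Msln (mesothelin) at 1.14 ± 0.12, Mbp (myelin basic protein) at 1.10 ± 0.10, Map7d2 (microtubule-associated) at 0.99 ± 0.06 and Gprasp2 at 0.97 ± 0.10. Of these 10 largest rises, 7 lie on the X chromosome. The other large falls were Tmem132d at −1.49 ± 0.09, Pou2f3 (a transcription factor of tuft cells) at −1.45 ± 0.11 and Cemip (hyaluronan breakdown) at −1.38 ± 0.08. On the deposited scale the median gene lay 0.15 higher in dcIDR, and 1856 genes were higher and 595 lower. That count of 2451 became 3903 without WT library B of 40 min, 4040 without dcIDR library A of 20 min, 1574 without WT library A of 60 min, 1533 without dcIDR library B of 40 min and 1606 without dcIDR library B of 60 min. It became 7763 without the 10 min libraries and 1551 without genes of chromosomes 4, 6, 8, 11 and X.

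Of the 23 lists, 9 moved together in dcIDR by the camera test, and 3 of these passed with an estimated correlation as well. The 2-cell-like genes fell in 20 of 21 members with none higher, 20 when adjusted over the list alone (adjusted p = 1.98e-46), to a list median of −1.86 that was −1.69 on the deposited scale. Beside the Zscan4 genes, Gm4340 lay at −2.66, Tcstv3 at −2.11, Usp17lb at −2.02 and Sp110 at −1.04, and Zfp750 alone did not pass, at −0.07; these 5 members were named after their values were seen. The Zscan4 and Usp17l genes have near-identical copies whose reads may be divided among them. Cholesterol synthesis genes rose in 15 of 25 with none lower, 17 when adjusted over the list alone (adjusted p = 1.48e-08), with the regulator gene Srebf2 at 0.34 ± 0.04, Msmo1 at 0.37 ± 0.05 and Sc5d at 0.55 ± 0.08. Imprinted and germline genes were higher in 13 and lower in 3 of 24, 19 when adjusted over the list alone (adjusted p = 5.19e-05). Among them rose Peg3 (imprinted, 0.60 ± 0.04), Stag3 (meiotic cohesin, 0.43 ± 0.04) and Taf7l, and Grb10 (an imprinted adaptor) fell by 0.55 ± 0.05. As deposited, 18 of the 2-cell-like genes were lower and 0 higher, 8 cholesterol synthesis genes higher and 0 lower, and 10 imprinted and germline genes higher and 2 lower.

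The other 6 list calls in dcIDR did not pass with an estimated correlation, and 5 of them have a median that turns positive on the deposited scale. Glycolysis genes were higher in 10 and lower in 1 of 23, 13 when adjusted over the list alone (adjusted p = 0.00202, and 0.287 as an adjusted p with an estimated correlation), with the X-linked Pgk1 at 0.65 ± 0.04, Pfkm at 0.59 ± 0.07 and Gpi1 at 0.31 ± 0.03. Histone modifying enzymes were higher in 7 and lower in 20 of 46, 28 when adjusted over the list alone (adjusted p = 0.0132, and 0.287 as an adjusted p with an estimated correlation; median −0.08, deposited 0.09), with the demethylase genes Kdm3a at −0.45 ± 0.03 and Kdm2b at −0.45 ± 0.04 and the X-linked Kdm5c at 0.41 ± 0.03. Naive pluripotency genes were higher in 4 and lower in 13 of 27, 20 when adjusted over the list alone (adjusted p = 0.0137, and 0.446 as an adjusted p with an estimated correlation; median −0.12, deposited 0.05), with Lin28a (a let-7 regulator, chromosome 4) at −0.99 ± 0.08 and Fbxo15 at −0.41 ± 0.04. RNA polymerase II and elongation genes were higher in 1 and lower in 17 of 42, 20 when adjusted over the list alone (adjusted p = 0.0137, and 0.446 as an adjusted p with an estimated correlation; median −0.11, deposited 0.06), with Hexim1 (an inhibitor of P-TEFb) at −0.41 ± 0.05 and Cdk12 at −0.24 ± 0.03. Neural markers were lower in 3 of 9 with none higher, 3 when adjusted over the list alone (adjusted p = 0.0342, and 0.0514 as an adjusted p with an estimated correlation; median −0.13, deposited 0.04), with Tubb3 at −0.88 ± 0.07 and Nes at −0.41 ± 0.05. Cell cycle genes were higher in 3 and lower in 15 of 31, 19 when adjusted over the list alone (adjusted p = 0.0346, and 0.446 as an adjusted p with an estimated correlation; median −0.12, deposited 0.05), with Cdk2 at −0.34 ± 0.05 and Mcm2 at −0.26 ± 0.04. Without the genes of chromosomes 4, 6, 8, 11 and X, on which Tubb3, Mcm2 and Hexim1 lie, the neural and cell cycle lists no longer passed (adjusted p = 0.565 and 0.367), and without the 10 min libraries neither did the cell cycle list (0.215) nor the histone modifying enzymes (0.0788). The naive list and the histone modifying enzymes passed without these chromosomes also with an estimated correlation (adjusted p = 0.00281 and 0.0129), as did the neural list without the 10 min libraries (0.0222). Formative and primed genes and ribosomal protein genes did not pass by camera with all genes and libraries. They passed as lower in these settings at the preset correlation alone (adjusted p = 0.0353 and 0.0495, and 0.0353 and 6.56e-05). With an estimated correlation the adjusted p was 0.223 and 0.501 for the former and 0.657 and 0.501 for the latter, and with all genes and libraries their medians were 0.05 and 0.08 as deposited. On that scale the calls numbered 2 higher and 0 lower for histone modifying enzymes, 2 and 1 for naive genes, 1 and 0 for RNA polymerase II and elongation genes, 2 and 0 for cell cycle genes, 6 and 0 for glycolysis genes and 0 and 2 for neural markers.

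The other 14 lists did not pass in dcIDR. Formative and primed genes were higher in 3 and lower in 8 of 20 (13 when adjusted over the list alone, adjusted p = 0.0802), with Lefty2 at −1.31 ± 0.06 and Lefty1 at −0.71 ± 0.11. ATF4 targets were higher in 8 and lower in 3 of 26 (12 when adjusted over the list alone, adjusted p = 0.0666), with Ddit3 (the stress factor CHOP) at 0.41 ± 0.07 and Atf4 itself at −0.22 ± 0.04, a call lost as deposited (−0.049, adjusted p = 0.870). Without genes of chromosomes 4, 6, 8, 11 and X the ATF4 list passed as higher (adjusted p = 0.0472, and 0.223 as an adjusted p with an estimated correlation). Genes for m6A writers, erasers and readers were higher in 2 and lower in 9 of 22 (11 when adjusted over the list alone, adjusted p = 0.0673), with Igf2bp1 at −0.44 ± 0.03. Endoderm and mesoderm markers were higher in 2 and lower in 4 of 15 (7 when adjusted over the list alone), with the laminin gene Lama1 at −0.57 ± 0.04, and trophoblast markers in 3 and 1 of 10 (5), with Gata2 at 1.51 ± 0.17 and Krt8 at −2.23 ± 0.33. MAPK feedback targets were higher in 2 and lower in 5 of 17 (7 when adjusted over the list alone), with Spry2 (an inhibitor of receptor signalling) at −0.86 ± 0.07, Ccnd1 (cyclin D1) at −0.64 ± 0.06 and Myc at −0.96 ± 0.15. Immediate early genes were higher in 7 and lower in 4 of 25 (11 when adjusted over the list alone), Wnt targets in 3 and 3 of 12 (6), p53 targets in 4 and 3 of 23 (8), and fibroblast markers in 2 and 2 of 9 (5). Interferon genes were lower in 5 of 19 with none higher (5 when adjusted over the list alone, adjusted p = 0.405). Ribosomal protein genes were higher in 1 and lower in 10 of 89 (10 when adjusted over the list alone, adjusted p = 0.0582), replication-dependent histones in 6 and 6 of 63 (10), and genes named Zfp in 50 and 78 of 347 (136). As deposited, the calls turned to 4 higher and 2 lower for formative and primed genes, 2 and 1 for endoderm and mesoderm markers, 1 and 0 for interferon genes and for ribosomal protein genes, and 23 and 5 for Zfp genes. Replication-dependent histones turned from even to 8 higher and 0 lower. Of the m6A list no gene passed as deposited (limma), 3 having an unadjusted p under 0.05, and its median was 0.12 against −0.048. The other lists had 7 higher and 0 lower (ATF4 targets), 5 and 1 (immediate early genes), 3 and 1 (trophoblast markers), 2 and 3 (MAPK feedback targets), 2 and 1 (Wnt targets), 2 and 0 (p53 targets) and 1 and 1 (fibroblast markers).

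Regional shifts were seen in dcIDR as well. The 464 genes of the X chromosome with a mean level of at least 50 had a median difference of 0.25, 239 being higher and 42 lower. Repeat windows placed the shift at 96 to 109 Mb (0.34), 129 to 140 Mb (0.31) and 149 to 167 Mb (0.47) of the X chromosome (GRCm39). The median over all X windows was 0.35 at 10 min but −0.03, 0.07 and 0.04 at 20, 40 and 60 min. Genes of the X chromosome had medians of 0.21, 0.34, 0.21 and 0.26 at the 4 times. On chromosome 4, 4 adjacent windows of 0.25 Mb from 133000001 to 134000000 fell by 0.77 against a flanking median of 0.04. It was the longest of 13 falling runs, the other 12 being of 2 windows. Genes of chromosomes 8, 12 and 6 above that level had medians of −0.15, −0.13 and −0.11.

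Set against each other, the mutants differed at more genes than either did from WT, relative to the median gene. Dcdc2a, Slc13a5 and Sntg1 were higher in dcIDR than in KO by 3.44 ± 0.08, 2.83 ± 0.06 and 2.76 ± 0.12, as were Scml2 by 3.01 ± 0.09 and the noncoding Platr15 by 2.76 ± 0.11. Lefty2 was lower in dcIDR, at −2.70 ± 0.06, as were Pou2f3 at −2.78 ± 0.11, and Zscan4a and Zscan4c at −2.92 ± 0.11 and −2.72 ± 0.09. In all, 4927 genes were higher and 5234 lower in dcIDR than in KO (limma), 763 and 777 by more than 2-fold. On the deposited scale the median gene lay at −0.13 in dcIDR against KO, and 1638 genes were higher and 4402 lower, a balance that turned to 4897 and 1346 without the 10 min libraries. Genes of chromosomes 6 and 8 with a mean level of at least 50 had medians of −0.51 and −0.49 in this comparison, and genes of both chromosomes took part in its count.

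Whether both mutants moved the same genes was then asked. Across the 22448 genes the differences of KO and of dcIDR from WT had a Pearson r of 0.028 and a Spearman rho of 0.061, where genes are not independent replicates. The same WT libraries enter both differences, and simulated mutants without any change gave r = 0.50. The differences had the same sign in 53% of genes, against 66.8% in the simulation. Noise and the shared WT libraries alone set the simulated r and share. Real differences also hold gene changes, so their r and share cannot be measured against these values. The covariance was 0.00443 against 0.0147 in the simulation, and with the WT libraries split between the mutants r was −0.061 and −0.062 over 19600 genes. Both mutants had 541 genes higher and 898 lower, against 403 and 638 for independent lists, and 1498 genes passed in opposite directions, against 1024 for independent lists. Lefty1, Lefty2 and the Zscan4 genes were among the latter. Independent lists allow neither for the shared WT libraries nor for the shifts of whole chromosomes. Of 782 genes of chromosome 6 with a mean level of at least 50, 588 were higher in KO and 263 lower in dcIDR. For the 780 of chromosome 8 these were 576 and 340. The excess in opposite directions cannot be told apart from these shifts. Without genes of chromosomes 4, 6, 8, 11 and X r was 0.061.

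Labelling time changed the genotype difference of 1 gene in KO. Bhlhe40, a circadian and hypoxia-responsive transcription factor gene on chromosome 6, lay 0.14 above WT at 10 min, 0.78 at 20 min, 1.30 at 40 min and 2.01 at 60 min (limma F test, adjusted p = 0.00917). In simulated data, with noise independent between genes, this test made 9 false calls for KO. In dcIDR 1822 genes (8.12%) had a difference that depended on labelling time, and 1058 of them deviated most at 10 min and 679 at 20 min. This count was 17 with 1 term in log2 minutes, 855 without WT library B of 20 min, and 925 and 1009 without dcIDR library A or B of 20 min. The KO count ranged from 0 to 159 when 1 library was left out, with 159 without WT library A of 10 min. The linker histone gene Hist1h1b moved from −0.60 and −0.70 at 10 and 20 min to 0.30 and 0.54 at 40 and 60 min, and Klf3, a zinc finger repressor gene, from −0.43 and −0.34 to −1.29 and −1.28. Ccnl1 (cyclin L1) lay at −0.80 at 10 min and 0.43 at 20 min. These 4 genes were named after their values were seen. Of 100 splits of the 16 libraries within labelling time, 11 gave at least the 1 gene of KO and 9 at least the 1822 of dcIDR, the real split included. The other splits were fitted without setting aside the spread of unclear library splits. Fitted like them, the real split gave 10 genes in KO and 2017 in dcIDR. Without the 10 min libraries 452 genes passed in dcIDR and 0 in KO, where 2927 passed an unadjusted p under 0.05 (limma).

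Longer labelling raised the level of nearly every gene. On the deposited scale 22196 of 22448 genes rose with labelling time and 2 fell (limma), by a median of 0.84 per doubling of the time. Relative to the median gene, 7607 rose and 4014 fell. The ratios to 10 min in the authors' deposited table had medians of 0.93, 2.01 and 2.09 at 20, 40 and 60 min in WT, 0.42, 1.20 and 1.67 in KO, and 2.26, 2.89 and 2.72 in dcIDR.

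Repeat RNA was compared by summing the loci of each class and family name. In KO 4 of 60 families were lower relative to the mRNA median and none higher (limma), but 1 with a pseudocount of 10 and 1 without the 10 strongest loci of each family. The endogenous retrovirus families LTR/ERV1 and LTR/ERVK lay at −0.14 ± 0.03 (adjusted p = 0.00609) and −0.10 ± 0.03 (adjusted p = 0.0250), Satellite/Y-chromosome at −0.15 ± 0.03 and repeats of unknown class at −0.17 ± 0.03. On the deposited scale all 4 lay above WT, by 0.17, 0.21, 0.16 and 0.14, and no family passed, with 37 of 60 at an unadjusted p under 0.05 (limma). In dcIDR no family passed against WT (limma), 7 having an unadjusted p under 0.05. Without the 10 min libraries 4 passed, all higher, and without dcIDR library B of 10 min 6 passed, 1 higher and 5 lower. The ERVL family, which holds the retroviruses active in the 2-cell embryo, lay at −0.12 ± 0.04 in dcIDR against WT, which did not pass (adjusted p = 0.145) and turned to 0.05 as deposited. Against KO it lay at −0.16 ± 0.04 (adjusted p = 0.0113), and at −0.30 as deposited. In that comparison 3 families were higher and 7 lower, among them LTR/ERV1 at 0.15 ± 0.03. They numbered 5 relative to the families' own median, 3 without the 10 strongest loci and 6 without KO library B of 20 min. However, none passed on the deposited scale, where 5 had an unadjusted p under 0.05 (limma) and LTR/ERV1 lay at 0.01. LINE/L1, with 21% of all repeat reads, differed from WT by 0.00 in KO and −0.05 in dcIDR (0.31 and 0.12 as deposited), and neither passed.

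At single repeat copies, relative to the median locus of each library, 8301 of 306027 loci were higher and 12584 lower in KO than in WT, and 3091 higher and 7915 lower in dcIDR (limma). The dcIDR count of 11006 became 7123 without WT library A of 60 min, 7267 without dcIDR library B of 40 min and 17455 without dcIDR library A of 10 min. With a 5 times higher filter the counts were 10551 in KO and 5922 in dcIDR, and the KO count was 32773 with a pseudocount of 10. Among ERVK copies 639 were higher and 1938 lower of 18457 in KO. An ERVK copy on chromosome 17, at 80872449 to 80875243 (GRCm39), fell by 3.00 ± 0.09. Among ERVL copies 72 were higher and 751 lower of 6701 in dcIDR. An ERV1 copy on chromosome 4, at 66822412 to 66824662, fell by 2.50 ± 0.07 in KO and rose by 1.43 ± 0.07 in dcIDR, and an L1 copy on chromosome 13, at 80517790 to 80523503, fell by 2.67 ± 0.15 in dcIDR. These 3 copies were named after their values were seen. Chromosome 6 alone held 3199 of the loci higher in KO and 214 of those lower, chromosome 11 held 1624 and 469, and chromosome 8 held 1607 and 152. Without loci of chromosomes 4, 6, 8, 11 and X, 1353 were higher and 9041 lower in KO, and 6310 passed in dcIDR. Libraries stayed centred on the median of all loci, and the kept autosomes had KO medians from −0.09 (chromosome 1) to −0.05 (chromosome 5). The excess of lower loci in KO cannot be told apart from this common offset.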

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

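The tests of the 10 min totals, of single strong genes on chromosomes 6 and 8, of other fallen runs of windows and of a response to the loss of ALKBH5 were chosen after the result was seen. The difference of dcIDR from WT in labelled repeat RNA at the later times minus that at 10 min was 1.06 on the log2 scale and passed its test, which put it among the results for a closer look. So did the gene counts with a genotype difference that depended on labelling time, 1 in KO (Bhlhe40) and 1822 in dcIDR.

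The totals at 10 min differed from WT by 0.73 in KO and by −0.58 in dcIDR. Counting error of the spike-in reads is too small an explanation, at 2.06% of the dcIDR difference. Spike-in reads varied with an SD of 0.491 (log2) over the libraries of all times, which cannot decide whether sequencing depth mattered at 10 min. At 10 min the dcIDR libraries had 15998 and 12025 spike-in reads and 4000675 and 3133126 mRNA-table reads. The WT libraries had 23382 and 11310 spike-in reads and 10248699 and 3773847 mRNA-table reads, so this explanation stays open. The 10 min libraries carried 79.0% of the difference between dcIDR and WT in the median deposited ratio at 60 min, 56.8% at 40 min and 37.3% at 20 min, so the 60 min ratio may largely reflect them, and that at 20 min less so. A difference in labelling or capture of these dishes cannot be told apart from one of the genotype, the later totals differing by 0.35 with 1 pair of dishes per genotype and time.

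The genes of chromosomes 6 and 8 lay above WT in KO. A few strong genes are not enough, as 86.2% of all their tested genes lay above the median gene, and the shift did not depend on labelling time, its median having a range of 0.041 over the 4 times. A changed copy number of these chromosomes may explain it, which their windows leave open. Of these windows 72.8% lay over 0.2 above the other autosomes, between the bounds of 50 and 80% set beforehand. For the last part of the X chromosome in dcIDR 51.9% did. The test did not cover the block of chromosome 11 in KO, where 42 windows had a median of 0.40 against −0.03 elsewhere on that chromosome. For the block of 4 adjacent windows on chromosome 4 in dcIDR, which fell by 0.77 against 0.04 in its flanks, a deletion cannot be told apart from lower transcription, since 12 other runs of 2 windows fell by over 0.5 as well. A response to the loss of ALKBH5 stays open, since each genotype is 1 line; the same genes had a median of −0.12 in dcIDR.

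The 2-cell-like genes fell in dcIDR. Loss of 1 gene cluster as the source for the list is argued against by fallen members on 9 chromosomes. The 20 genes that neighbour the Zscan4 cluster had a median of −0.037, with single genes from −1.97 to 0.30. A loss confined to the cluster and its nearest genes would not show in that median. The 8 members outside the Zscan4, Tcstv, Usp17l and Tdpoz families had a median of −1.40. They were set apart by name alone, and whether they have near-identical copies was not examined, Gm4340 being among them. This median therefore cannot decide whether reads shared between copies play a part. A dependence on labelling time is argued against by a range of 0.46 over the 4 list medians. A lower share of cells in the 2-cell-like state in this line may be the source, a hypothesis that was not tested, and it cannot be assigned to the deletion with 1 line per genotype.

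Counts were set against splits of the 16 libraries of a comparison within labelling time, of which 648 are possible and 100 were drawn, or 25 for single loci. The real counts are those of the main fit, while the other splits were fitted without setting aside the spread of unclear library splits. For genes relative to the median the real split ranked first in all 3 comparisons. This is the best rank that 100 drawn splits allow, and it was not adjusted over these tests. Splits that mix the genotypes also add a real difference to the spread, which lowers their counts. The rank therefore speaks against chance only within these draws, and a difference between lines or dishes would give the same rank. Only 1 of 100 splits gave as many, the real one, with 7286 against at most 4508 in KO, 6361 against 3838 in dcIDR and 10161 against 6485 between the mutants. Fitted like the others, the real split gave 7359 in KO, 6442 in dcIDR and 10219 between the mutants. On the deposited scale 2 splits reached the 7022 genes of KO, the real one included (7037 fitted like the others), with a highest other of 8415. Of these genes 90.5% were higher, and the KO total itself did not pass (adjusted exact permutation p = 0.144), so chance is not excluded there. For dcIDR on that scale 4 of 100 drawn splits reached 2451, the real one included (2450 fitted like the others), with a highest other of 12842. The dcIDR total did not pass either (adjusted exact permutation p = 0.537), so chance is not excluded for dcIDR. Chance cannot be excluded on that scale for dcIDR against KO, where 9 splits reached 6040 genes and another gave 16920. The same holds for dependence on labelling time, where 11 splits reached the 1 gene of KO and 9 the 1822 of dcIDR, the highest others being 5247 and 6774. There the real split, fitted like the others, gave 10 genes in KO and 2017 in dcIDR. For repeat families 2 splits reached the 4 of KO, the real one included (highest other 11), and 6 the 10 between the mutants (highest other 22). Chance is excluded for neither, since the KO rank was not adjusted over these tests and no KO family passed as deposited (limma). For dcIDR, with 0 families (limma, 7 at an unadjusted p under 0.05; highest other 13), all 100 splits reach 0 by construction, so nothing can be read from them. For single loci 1 of 25 splits, the real one, gave as many, with 20885 in KO (highest other 0) and 11006 in dcIDR (highest other 1031). Its loci numbered 20891 and 11012 when fitted like the others. Other splits with several times the real count may reflect a structure of these libraries beyond genotype, which was not tested.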

How the results depend on the processing

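The settings that leave out the 10 min libraries or the genes of chromosomes 4, 6, 8, 11 and X, and limma voom, were chosen after the result was seen. Where values were relative to the median, leaving out chromosomes kept the centring on all genes or loci. No paired analysis was possible because the deposited columns combine both replicates and the recovered libraries carry no replicate number. Count tests and TMM-type factors were left out, although the recovered reads would have allowed them; voom and quantile normalization were run. Of the alternative values of the main results, 464 of the planned and 30 of the added ones kept their direction and their side of the threshold, or lay within 1.5 times the count, while 46 planned and 15 added ones moved further, 2 planned ones came to pass and 2 added ones changed sign. The cause of the changes below was not tested, except that fewer genes, loci or libraries leave fewer to call.

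Relative to the median, KO against WT gave 4608 genes (1579 higher, 3029 lower) without those chromosomes, quantile normalization moved the share of higher genes in dcIDR from 40.7 to 48.4%, and without filter dcIDR gave 2799 higher and 2287 lower. On the deposited scale 90.5% of the changed genes were higher in KO against 47.9% relative to the median, and 75.7 against 40.7% in dcIDR. That scale gave 2960 genes in KO and 7763 in dcIDR without the 10 min libraries, and 3871, 1551 and 3345 in KO, dcIDR and dcIDR against KO without those chromosomes. Slopes with labelling time passed in 22198 genes as deposited. Dependence on labelling time was called in KO for 4 genes with a 5 times higher filter, 2 with a pseudocount of 10, 0 without the 10 min libraries and 0 without those chromosomes (limma, 2927 and 1756 at an unadjusted p under 0.05), and in dcIDR for 17 with 1 term in log2 minutes and 452 without the 10 min libraries. Without these libraries the difference of dcIDR from KO turned to 0.20 for mRNA and 0.23 for repeats.

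In KO 0 families passed as deposited (limma, 37 unadjusted), 1 with a pseudocount of 10 and 1 without the 10 strongest loci of each family. In dcIDR 4 passed without the 10 min libraries, all higher. Between the mutants 0 passed as deposited (limma, 5 unadjusted), 5 relative to the families' own median and 3 without the 10 strongest loci. Single loci numbered 10551 in KO and 5922 in dcIDR with a 5 times higher filter, 32773 in KO with a pseudocount of 10, and 10394 and 6310 without those chromosomes. With an estimated correlation 3 lists passed in dcIDR, 4 without the 10 min libraries and 5 without those chromosomes. The correlation of both mutants was −0.061 and −0.062 with WT split and 0.061 without those chromosomes.

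Leaving out 1 library at a time, which assumes that the lone library of a group varies like the others, gave 1533 to 4040 genes as deposited in dcIDR, 0 to 159 with dependence on labelling time in KO and 855 to 2433 in dcIDR. The KO count was 159 without WT 10 min A, 58 without KO 20 min A, 22 without KO 10 min A, 10 and 9 without dcIDR 10 min B and A, 4 without WT 20 min A, 2 without WT 40 min A, and 0 without WT 10 min B, either WT 60 min library, KO 10 min B or either KO 60 min library. The dcIDR count was 855 without WT 20 min B, 925 without dcIDR 20 min A and 1009 without dcIDR 20 min B. Totals of KO lay 0.22 to 0.37 above WT for mRNA and 0.23 to 0.38 for repeats, the highest, past the threshold, without WT 40 min B. Families in dcIDR numbered 0 to 6, with 6 without dcIDR 10 min B, 3 without WT 10 min A, KO 20 min A or KO 20 min B and 1 without dcIDR 10 min A, and between the mutants 6 to 14, with 6 without KO 20 min B. Loci in dcIDR numbered 7123 to 17455, with 7123 without WT 60 min A, 7267 without dcIDR 40 min B and 17455 without dcIDR 10 min A.

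Of 223 named gene results 146 held as deposited, 72 no longer passed and 5 changed sign, all in KO: Epha2 at 0.030, Ccnt2 at 0.034, Hist1h2bc at 0.023, Mcm7 at 0.064 and Fn1 at 0.0018. Without the filter on low levels, which raised the genes adjusted over from 22448 to 44971, 10 named calls no longer passed. No setting isolated what depth limits.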

Other observations

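All comparisons of this part were chosen after the result was seen. Arid1a, a subunit of the BAF chromatin remodelling complex on chromosome 4, differed from WT by −0.99 ± 0.04 in dcIDR (limma, relative to the median gene) and by 0.13 in KO. Lin28a, also on chromosome 4, differed by −0.99 ± 0.08 in dcIDR. Whether they lie inside the block was not analysed here, since the annotation used is of another build.

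Members of the imprinted and germline list beyond those named above differed in dcIDR by 1.46 (Asz1), 1.18 (Slc25a31) and 0.98 (Mael), all genes of germ cells, and Mest, an imprinted gene on chromosome 6, rose by 1.09 in KO. These members were named after their values were seen.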
